A study of Homo sapiens with 80 samples.

How the data were processed

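Poly(A) RNA from needle biopsies of 40 liver grafts was sequenced on a HiSeq3000 instrument after library preparation with a PrepX kit on an automated system, per the labels' protocols. Each recipient contributed a pre-transplant and a post-transplant library. The protocol text is the same for both times, places the biopsy after reperfusion and so does not describe the pre-transplant sampling further. The number in each sample's label gave the pair, and the label gave the time and the injury status, from which 4 groups were formed: IRI- pre-transplant and post-transplant (17 libraries each) and IRI+ pre-transplant and post-transplant (23 each). The replicate numbers used in the text count libraries within a group. The labels gave no sequencing batch or date. All libraries are from separate recipients apart from the pairing.

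The authors deposited 1 table of raw read counts per gene, not normalized, with a column per library. Per the submitters' processing notes, FastQC 0.11.8, STAR 2.7.1a, featureCounts 2.0.0 and the GRCh38 genome were used. Their settings, the annotation release, the use of strand and the treatment of reads that map to more than 1 place are not given in the sources used here. Reads of near-identical copies can therefore have been split, dropped or assigned to 1 copy, which makes values of the metallothioneins, HSPA6 and HSPA7, HSPA1A and HSPA1B, SAA1 and SAA2, ORM1 and ORM2 and the alpha globin genes uncertain. Genes that overlap on opposite strands, including the mitochondrial MT-ND6, are uncertain for the same reason. Of the 60498 gene identifiers, 56868 matched GENCODE release 29, from which symbols, gene types and GRCh38 coordinates were taken.

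Every column matched 1 sample (0 columns had none). No 2 columns were identical, and the highest Pearson correlation between any 2 libraries on log2 CPM was 0.982, so each library counted as its own sample. A check for mixed-up samples within pairs found 0 of 40 pairs that did not match, with 4 libraries close to the limit of the check. It compared a single trait, so it cannot see mix-ups between recipients who share that trait. Nor can it see exchanged pre and post labels within a pair. 532 features (Y-linked genes, XIST and TSIX) were left out of every test and table of genes. Total counts ranged from 7237415 to 32009394. At this depth the median SE of a log2 fold change was 0.121 for post against pre over both groups, 0.184 within IRI-, 0.158 within IRI+, 0.171 between the groups before and 0.172 after transplantation, and 0.242 for the difference of the changes. The most abundant 10 genes took between 16.9% and 35.7% of a library and protein-coding genes between 91.2% and 98.4%.

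Genes were tested in R 4.3.3 with edgeR 4.0.16. Genes with too few reads were removed with filterByExpr at its defaults, which left 16607, and libraries were scaled with TMM factors (0.7 to 1.373). A quasi-likelihood model with robust estimation was fitted to the 4 groups over all 80 libraries, so that all comparisons shared 1 estimate of the spread of a gene, and contrasts were tested with glmQLFTest and Benjamini-Hochberg adjustment over the tested genes of a contrast. A gene was called at an adjusted p under 0.05. There were 6 contrasts: post against pre as the mean of both groups, within IRI- and within IRI+, IRI+ against IRI- before and after transplantation, and the difference between the changes of the groups. The SE of a log2 fold change is its size divided by the square root of the F statistic. CPM values use TMM-scaled library sizes, log2 CPM adds a prior count of 2, and means are given with their SD over the libraries of a group.

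34 lists of genes, covering stress, inflammatory, metabolic and cell type markers, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over the lists of a contrast. Beside it, camera with an estimated correlation and fry were run. Fry asks whether the genes of a list move on balance in 1 direction and does not compare them with other genes. Of the 13 lists called post against pre, 5 held with an estimated correlation: immediate early, NF-kB-driven, heat shock, hypoxia-induced and p53 genes. For each list the measured members that rose, fell or did not pass were counted, with p adjusted over all genes and adjusted over the list alone. Some lists share members, such as SDS and TAT, TREM1 and THBS1, each in 2 lists. Cell type lists also hold genes that hepatocytes or other liver cells can express. The tests, groups, lists, naming rule and the alternative settings given first below were fixed before the data were examined.

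The genes named in the text were taken by rule. For each main comparison these were the 8 genes with the largest increase and the 8 with the largest decrease among those called with a mean log2 CPM of at least 2, which for post against pre also had to move that way in at least 75% of the pairs. Immunoglobulin and T cell receptor segments, HLA genes, genes with common germline deletions, clone names, pseudogenes, antisense and other noncoding names were left out. From each list up to 4 members with the largest change among those called with a mean log2 CPM of at least 0 were taken, or the 2 with the smallest p where none was called. Where fewer than 5 genes were called, the 5 with the smallest p were taken. Genes named outside this rule, among them FGF19, HSPA7, MTCYBP18 and members of gene families, were chosen after their values had been seen.

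The scripts were tested on simulated counts drawn from the real means and library sizes with a known set of genes changed. For post against pre over both groups (16494 genes), 67.2% of the genes changed 1.5-fold were recovered, 97% of those changed 2-fold and 98.4% of those changed 4-fold. The shares were 37.3%, 68.2% and 95.2% within IRI-, and 53.7%, 84.8% and 96.8% within IRI+. Between the groups before transplantation (16491 genes) they were 41.8%, 82.1% and 100%, between the groups after it (16498 genes) 58.2%, 80.6% and 96.9%, and for the difference of the changes (16498 genes) 22.4%, 46.3% and 83.1%. Between 2 and 8 unchanged genes were called, the changed list was called each time, and 0 of 33 unchanged lists were. Counts were drawn independently for each gene and without pair effects, so the simulation cannot show how the list test behaves on correlated genes. Apart from the changed genes, all 4 groups had the same mean and spread of a gene, so the shares do not compare the spread of the real groups. Regroupings of the real samples, described below, called lists with the preset correlation. Their medians were 10 lists post against pre, 10 before and 11 after transplantation and 9 for the difference of the changes.

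The pairing comes from the recipient numbers in the labels. Deviations of libraries from their group means correlated with a median of 0.484 between the libraries of a pair (range -0.0731 to 0.753, above 0.1 in 39 of 40 pairs), against a median of -0.0134 between libraries of different recipients. The model without the pairs is the one reported because no source used here says that the study blocked on them. The model with the pairs as a replicate block is an alternative, whose value stands beside a named gene or list where it changed the call. Counts of list members that passed come from the model without the pairs, which ignores the correlation within pairs. It called 5752 genes post against pre, against 8176 with the block. The list tests with the block ran camera on voom values and those without it on counts, so a changed list call can come from either. The other settings fixed in advance were DESeq2 1.42.0, limma-voom without a block and with the pair as a random block, median-ratio size factors, scaling by total counts alone, no filter on low counts, a mean CPM of at least 1, 2 surrogate variables from sva 3.50.0, estimation without robust weights, fits of only the groups compared, a threshold of 2-fold, and leaving out the 2 libraries with under 0.5 of the median total. Added after the data had been seen were fits without the 5 libraries that stood apart (more than 5 robust SDs on the second component or in mitochondrial share), without IRI+ pair 23, without both, with the block and without that pair, without 2 IRI- pairs high in MTCYBP18, with 17 of the 23 IRI+ pairs drawn 50 times, and without each library in turn.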

Results

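RNA was sequenced from needle biopsies of 40 transplanted human livers, each sampled before transplantation and again after reperfusion, giving 80 libraries. The recipients were labelled as having ischemia and reperfusion injury (IRI+, 23 pairs of biopsies) or not (IRI-, 17 pairs). The labels do not say how the status was assigned. Deposited counts summed to between 7237415 and 32009394 per library, with a median of 23623724. The group medians were 24453708 in IRI- and 23673448 in IRI+ before transplantation, and 22501716 in IRI- and 22918443 in IRI+ after it. Between 17677 and 23823 genes had at least 1 read in a library. The share of counts from mitochondrially encoded genes had a median of 13.9% and ranged from 9.26% to 38.6%. Its group medians were 12.9% (IRI-) and 14.1% (IRI+) before and 14.5% (IRI-) and 15.04% (IRI+) after transplantation. 5 libraries stood apart from the rest. IRI+ post-transplant library 4 held 7237415 counts, of which 27.8% were mitochondrial, IRI+ post-transplant library 15 held 38.6% and IRI- pre-transplant library 15 held 25.96%. That last library, IRI+ pre-transplant library 22 and IRI- post-transplant library 17 lay far out on the second principal component, which took 9.7% of the variance.

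The first comparison asked which transcripts differed after reperfusion. Genes of inflammatory signalling, transcription factors of the immediate early response and chaperones were far higher in the post-transplant biopsies of both groups. CCL20, a chemokine that attracts lymphocytes and dendritic cells, went from 0.845 ± 2.02 to 20.7 ± 26.7 CPM in IRI- (mean ± SD, n = 17) and from 0.27 ± 0.496 to 28.5 ± 37.9 CPM in IRI+ (n = 23), a log2 fold change over both groups of 5.65 ± 0.54 (SE, adjusted p = 7.94e-15, higher in 39 of 40 pairs). The IRI- pre-transplant mean of CCL20 is raised by library 14, at a log2 CPM of 3.09 against 0.707 for the next highest of its group. CXCL8, the neutrophil chemoattractant interleukin 8, rose by a log2 fold change of 4.69 ± 0.40 (adjusted p = 6.8e-17, 39 of 40 pairs), from 0.779 ± 0.921 to 26.9 ± 21.5 CPM in IRI- and from 1.66 ± 4.24 to 33.1 ± 44.9 CPM in IRI+, where pre-transplant library 23 stood at a log2 CPM of 4.39 for CXCL8 and the next highest at 1.08. The AP-1 transcription factor FOSL1 rose by 5.05 ± 0.39 (adjusted p = 1.62e-18, 39 of 40 pairs) and the stress-inducible chaperone HSPA6 by 5.37 ± 0.45 (adjusted p = 4.15e-17, 38 of 40 pairs). In the GRCh38 annotation CCL20 (ENSG00000115009) spans 227805739 to 227817564 of chromosome 2, CXCL8 (ENSG00000169429) spans 73740506 to 73743716 of chromosome 4, FOSL1 (ENSG00000175592) spans 65892049 to 65900573 of chromosome 11, and HSPA6 (ENSG00000173110) spans 161524540 to 161526910 of chromosome 1. The other large increases were those of the cytokine LIF (5.54 ± 0.46), C2CD4A (4.44 ± 0.44), the co-chaperone DNAJA4 (4.16 ± 0.31) and the transcription factor IRF4 (4.15 ± 0.44), each higher in at least 37 of 40 pairs.

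The decreases were smaller. SLC25A34, a gene of the mitochondrial carrier family (ENSG00000162461, chromosome 1, 15736405 to 15741396), went from 8.29 ± 5.71 to 3.25 ± 1.91 CPM in IRI- and from 10.4 ± 6.15 to 4.5 ± 2.89 CPM in IRI+, a log2 fold change of -1.28 ± 0.20 (adjusted p = 1.22e-07, higher in only 1 of 40 pairs). GIMAP7, a GTPase gene of lymphocytes (ENSG00000179144, chromosome 7, 150514830 to 150521073), went from 6.17 ± 1.71 to 3.03 ± 1.77 CPM in IRI- and from 6.99 ± 1.65 to 2.97 ± 1.53 CPM in IRI+ (-1.12 ± 0.13, adjusted p = 1.45e-11, higher in 3 of 40 pairs). HAND2, a transcription factor (-1.23 ± 0.20), LIME1, an adaptor of lymphocyte receptor signalling (-1.18 ± 0.23), C14orf132 (-1.16 ± 0.13), the sialyltransferase gene ST6GAL2 (-1.10 ± 0.21), CMTM4 (-1.07 ± 0.12) and IGIP (-1.06 ± 0.14) completed the 8 largest, each higher in 5 or fewer of the pairs.

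**Figure D1:**
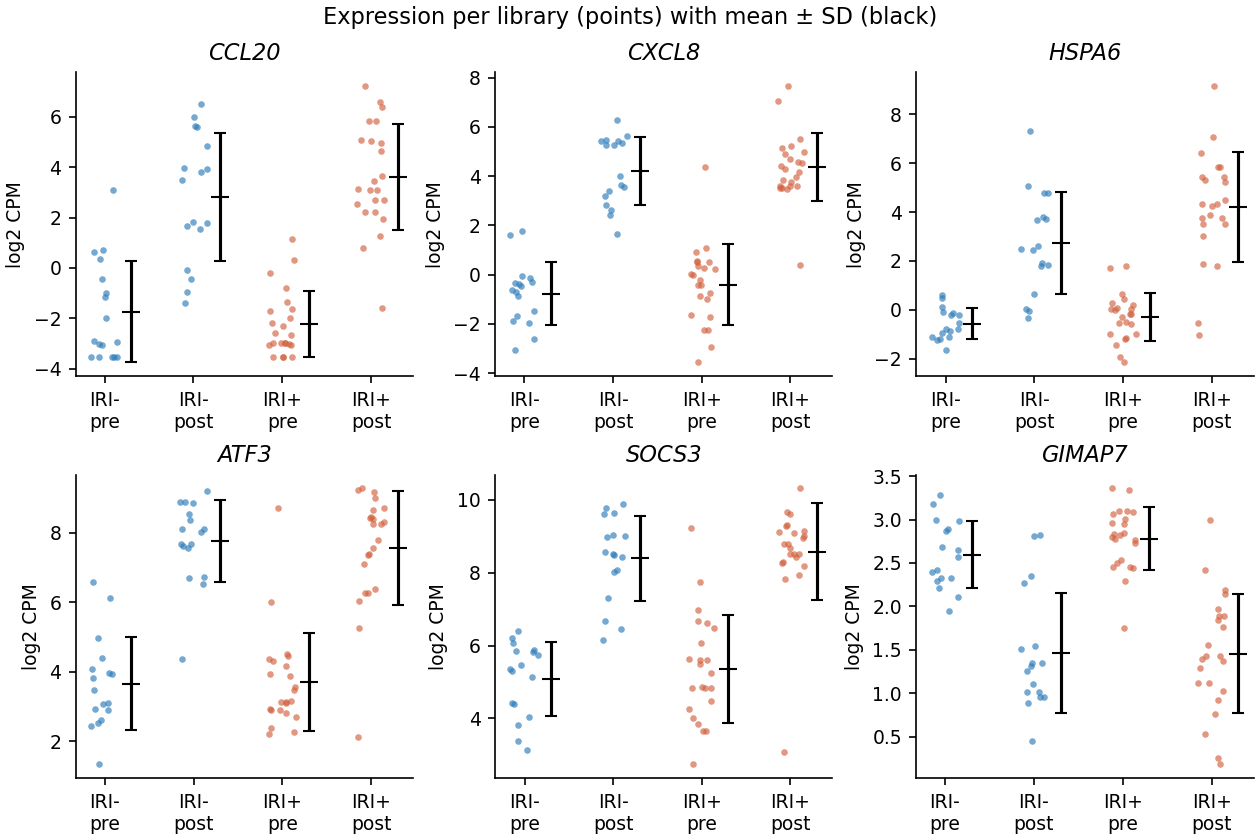
Log2 CPM (vertical axis) of CCL20, CXCL8, HSPA6, ATF3, SOCS3 and GIMAP7 in each of the 80 libraries (points) of the 4 groups (horizontal axis), with the mean ± SD of each group in black. CCL20, CXCL8, ATF3 and SOCS3 were higher after transplantation in 39 of 40 pairs and HSPA6 in 38, while GIMAP7 was higher in 3.

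In numbers, edgeR's quasi-likelihood test called 5752 of 16607 genes at an adjusted p under 0.05, of which 3106 were higher and 2646 lower after transplantation. Of these, 894 were at least 2-fold higher and 116 at least 2-fold lower. The split depended on scaling and on the model: 54% of the called genes were higher with TMM factors, and 34.3% of 6636 called genes when counts were scaled by library totals alone. On the TMM scale with the pairs as a replicate block, 8176 genes were called, 3688 higher (45.1%) and 4488 lower, and 46.2% of 8057 were higher in voom with the pair as a random block. The median log2 fold change over all genes was -0.043 with TMM factors and -0.134 with totals. Changes are given relative to the TMM scale.

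Immediate early genes, which cells transcribe within minutes of a stimulus, rose almost throughout. Of 27 measured members, 26 rose, with a median log2 fold change of 2.38 (camera adjusted p = 2.47e-35, and 0.0046 with an estimated correlation), and the same 26 passed when p was adjusted over the list alone. NR4A3, a nuclear receptor, rose by 3.93 ± 0.39 (adjusted p = 6.98e-14), FOSB by 3.90 ± 0.55 (adjusted p = 9.76e-09) and the stress-response factor ATF3 by 3.45 ± 0.37 (adjusted p = 6.45e-13), from 20 ± 24.9 to 273 ± 159 CPM in IRI- and from 31.5 ± 85.4 to 276 ± 188 CPM in IRI+. The IRI+ pre-transplant mean of ATF3 is raised by library 23, whose pair is described below, at a log2 CPM of 8.71 against 6.02 for the next highest of its group. CCN2, a matricellular growth factor, was the member that did not pass. Of 25 NF-kB-driven genes, 22 rose and 1 fell, with a median of 2.83 (adjusted p = 8.33e-30, and 0.0046 with an estimated correlation). Adjusted over the list alone, 23 rose and 1 fell. The cytokine genes CSF3 and IL6 were close to 0 before transplantation, so their levels are given in place of a fold. CSF3 went from 0.0075 to 2.18 CPM in IRI- and from 0.0495 to 2.1 CPM in IRI+ (adjusted p = 9.61e-17, higher in 38 of 40 pairs), and IL6 from 0.0317 to 2.83 and from 0.153 to 5.58 CPM (adjusted p = 8.72e-16, 39 of 40 pairs). The adhesion molecule VCAM1 was the member that fell.

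Acute phase genes as a list did not pass (median 0.05, mean 0.31, adjusted p = 0.122), although with the pairs as a replicate block, on voom values, the adjusted p was 0.0212. 3 of 20 members rose, the same 3 adjusted over the list alone: SOCS3, the feedback inhibitor of cytokine signalling (3.02 ± 0.29, adjusted p = 1.27e-14), the protease inhibitor SERPINA3 (1.90 ± 0.23) and the lipopolysaccharide binding protein LBP (0.53 ± 0.17, adjusted p = 0.00961). Of 19 interferon-stimulated genes, 5 rose and 1 fell, also when adjusted over the list alone. GBP1 (1.31 ± 0.17), MX2 (1.19 ± 0.22) and OASL (1.10 ± 0.21) were among those that rose, and IFIT3 fell (-0.44 ± 0.12, adjusted p = 0.00249). That list's median was -0.04 and its mean and test were positive (adjusted p = 0.48). Of 16 Toll-like receptor and danger signal genes, 6 rose, among them the myeloid receptor TREM1 (2.82 ± 0.33), the inflammasome sensor NLRP3 (1.67 ± 0.24), TLR2 (0.79 ± 0.14) and the ATP receptor P2RX7 (0.70 ± 0.15). The list did not pass (median 0.01, mean 0.37, adjusted p = 0.293), and adjusted over the list alone 6 rose and 1 fell. Coagulation and fibrinolysis regulators rose in 8 of 16 cases, also over the list alone (median 0.44, adjusted p = 4.41e-06, 0.0674 with an estimated correlation). They included the urokinase receptor PLAUR (3.39 ± 0.27), the adhesive glycoprotein THBS1 (2.84 ± 0.23) and urokinase itself, PLAU (2.56 ± 0.26).

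All 15 measured heat shock and chaperone genes rose, also when adjusted over the list alone (median 1.22, adjusted p = 2.75e-19, and 0.0123 with an estimated correlation). Besides HSPA6, the largest changes were those of DNAJB1 (3.37 ± 0.24, adjusted p = 6.28e-20, higher in 39 of 40 pairs), the co-chaperone BAG3 (3.35 ± 0.25) and HSPH1 (2.96 ± 0.24). The inducible pair HSPA1A and HSPA1B were not among the measured members: over all 80 libraries HSPA1A held 7 reads in total and HSPA1B held 0, against 1048594 reads for HSPA8, and how the counting treated near-identical copies is not given in the sources used here. Of 8 metallothioneins, which bind zinc and copper, all 8 rose, also over the list alone, with a median of 1.17 (adjusted p = 5.29e-05, 0.269 with an estimated correlation). MT1A rose by 1.56 ± 0.30, MT1M by 1.47 ± 0.29, MT2A by 1.33 ± 0.18 and MT1E by 1.20 ± 0.20. Reads of these genes can be shared between close copies.

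The unfolded protein and integrated stress response list rose on balance (median 0.34, adjusted p = 0.00938, 0.337 with an estimated correlation). 7 of its 17 members rose and 1 fell, or 9 and 1 adjusted over the list alone. PPP1R15A, which restores translation after stress, rose by 2.50 ± 0.20 (adjusted p = 5.61e-18), the glutathione-degrading enzyme CHAC1 by 2.33 ± 0.39, DDIT3 by 1.20 ± 0.18 and SESN2 by 0.51 ± 0.10. SEL1L, of the degradation machinery of the endoplasmic reticulum, fell. Hypoxia-induced genes rose in 10 of 19 cases, or 11 over the list alone, with a median of 0.42 (adjusted p = 1.66e-05, and 0.0447 with an estimated correlation). They were led by the vasodilator peptide ADM (2.10 ± 0.17, adjusted p = 9.29e-18), ANKRD37 (2.10 ± 0.25), the glycolytic regulator PFKFB3 (1.92 ± 0.18) and HILPDA (1.27 ± 0.19). Of 17 p53 and cell death genes, 12 rose, also over the list alone (median 0.83, adjusted p = 5.65e-11, and 0.0046 with an estimated correlation). CDKN1A, an inhibitor of the cell cycle, rose by 2.82 ± 0.23 (adjusted p = 9.73e-18, 39 of 40 pairs), the survival genes BCL2A1 by 2.81 ± 0.29 and MCL1 by 1.62 ± 0.13, and the stress cytokine GDF15 by 1.91 ± 0.32. NRF2 and oxidative stress genes did not pass as a list (median 0.15, adjusted p = 0.12, and 0.032 with the pairs as a replicate block, on voom values). 6 of 16 rose, 7 over the list alone, among them SRXN1 (0.79 ± 0.15), the heme oxygenase HMOX1 (0.78 ± 0.18), GCLM (0.59 ± 0.15) and SQSTM1 (0.53 ± 0.09).

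Glucocorticoid-induced genes rose in 10 of 16 cases, also over the list alone (median 0.73, adjusted p = 1.66e-05, 0.193 with an estimated correlation). TIPARP rose by 2.27 ± 0.17, FAM107A by 1.38 ± 0.18 and the transcription factor CEBPD by 1.32 ± 0.18. Of 16 core clock genes, 7 rose and 3 fell, also over the list alone, with a median of 0.16 (adjusted p = 0.0254, 0.49 with an estimated correlation, and 0.118 with the pairs as a replicate block, on voom values). The repressors BHLHE40 (2.14 ± 0.22), NR1D1 (1.95 ± 0.23) and PER2 (1.91 ± 0.16) rose, whereas TEF (-0.82 ± 0.15), CLOCK and BMAL1 fell.

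Lists of hepatocyte genes had small median changes. In the model without the pairs, none of 16 hepatocyte secreted proteins passed the test (median 0.01, test in the opposite direction, adjusted p = 0.975, 0 over the list alone). SERPINA1, the inhibitor of neutrophil elastase, had a log2 fold change of 0.10 ± 0.12 (adjusted p = 0.538) and the heme carrier HPX 0.07 ± 0.07 (adjusted p = 0.5). None of 15 drug-metabolizing cytochrome P450 genes passed either, with 0 over the list alone (median -0.09, adjusted p = 0.676). With the pairs as a replicate block, CYP3A43 (-0.47, adjusted p = 0.000165) and CYP2A6 (-0.30, adjusted p = 0.000122) were lower, where the test without the block gave adjusted p of 0.309 and 0.493. Only the named members of these lists were followed with the block, so others can have passed it. Of 18 bile acid genes, 1 rose, also over the list alone (median -0.08, mean 0.34, adjusted p = 0.975). It was FGF19, the hormone that represses bile acid synthesis, which went from 0.00403 ± 0.0166 to 1.56 ± 2.41 CPM in IRI- and from 0.0156 ± 0.0379 to 2.04 ± 3.72 CPM in IRI+ (adjusted p = 2.06e-16, higher in 34 of 40 pairs).

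Gluconeogenesis and fasting genes rose in 6 of 18 cases and fell in 1, also over the list alone (median 0.27, adjusted p = 0.147). SDS, an enzyme of serine catabolism (1.17 ± 0.24, higher in 39 of 40 pairs), IGFBP1 (1.13 ± 0.32), the coactivator PPARGC1A (1.0 ± 0.18) and SLC25A25 (0.97 ± 0.23) rose and the fatty acid sensor PPARA fell. Of 16 lipid and cholesterol synthesis genes, 4 rose and 2 fell, also over the list alone (median 0.15, adjusted p = 0.293). INSIG1 rose by 0.79 ± 0.16. The fatty acid synthesis genes ACACA (-0.47 ± 0.13) and ELOVL6 fell. Urea cycle and amino acid genes rose in 2 of 15 cases, also over the list alone (median -0.05, mean 0.08, adjusted p = 0.812), SDS and ASL (0.28 ± 0.10, adjusted p = 0.0192, 0.133 with total-count scaling). Of 18 cell cycle genes 1 passed, AURKA (0.46 ± 0.18, adjusted p = 0.0455, 0.0976 with total-count scaling and 0.126 with voom), and 0 passed over the list alone (median 0.39, adjusted p = 0.666).

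Markers of cell types moved apart. Of 18 neutrophil markers, 15 rose, also over the list alone, with a median of 1.11 (adjusted p = 0.00433, 0.784 with an estimated correlation), which was 0.66 (adjusted p = 0.00203) without IRI+ post-transplant library 15. PROK2 rose by 2.09 ± 0.39, the formyl peptide receptor FPR2 by 1.96 ± 0.27 and the protease MMP9 by 1.94 ± 0.35. Monocyte markers rose in 6 of 12 cases and fell in 1, also over the list alone (median 0.52, adjusted p = 0.000273, 0.228 with an estimated correlation), led by CD300E (2.96 ± 0.29), VCAN (1.92 ± 0.25) and FCN1 (1.57 ± 0.25), while the macrophage receptor CSF1R fell. Cholangiocyte markers rose in 6 of 12 cases, or 8 over the list alone (median 0.68, adjusted p = 1.66e-05, 0.188 with an estimated correlation). CLDN4 rose by 2.91 ± 0.26 and the keratins KRT19 by 2.23 ± 0.23 and KRT7 by 1.49 ± 0.18. The per-pair change averaged over a list was 0.98 ± 0.59 (SD, n = 40, higher in 39 pairs) for cholangiocyte, 0.97 ± 0.76 (38 pairs) for monocyte and 0.69 ± 1.26 (29 pairs) for neutrophil markers, against -0.02 ± 0.72 (19 pairs) for T and NK cell markers.

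T and NK cell markers went both ways, 3 up and 5 down of 18, also over the list alone (median -0.02, mean 0.12, test downward, adjusted p = 0.774). The cytotoxic genes GZMB (2.74 ± 0.38), GNLY (1.27 ± 0.29) and PRF1 (1.12 ± 0.21) rose, while CD3E of the T cell receptor complex (-0.72 ± 0.18), CD2, CD27, GZMA and GZMK fell. Of 12 Kupffer cell markers, 2 rose and 1 fell, also over the list alone (median -0.18, mean 0.05, test downward, adjusted p = 0.761), with SLC11A1 at 1.19 ± 0.23 and MS4A7 at -0.42 ± 0.13. None of 8 B and plasma cell markers passed, with 0 over the list alone (median -0.37, adjusted p = 0.48). JCHAIN was at -0.54 ± 0.23 (adjusted p = 0.0571, and 0.00848 with the pairs as a replicate block). Red blood cell markers had 1 of 7 lower, CA1 (-1.22 ± 0.47, adjusted p = 0.0349, 0.0641 without a filter on low counts and 0.0876 with surrogate variables), and 0 over the list alone (median -0.80, adjusted p = 0.48). Of 5 platelet markers, ITGB3 rose (1.25 ± 0.24), also over the list alone (median 0.45, adjusted p = 0.692).

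None of 12 sinusoidal endothelial markers passed, with 0 over the list alone (median -0.09, adjusted p = 0.48). With the pairs as a replicate block CLEC1B (-0.26 ± 0.14 without the block) had an adjusted p of 0.000341 in place of 0.141, and FCGR2B 0.00172 in place of 0.259. Of 13 vascular endothelial markers, KDR (0.34 ± 0.14) and ESAM (0.26 ± 0.09) rose and EGFL7 fell (-0.26 ± 0.10), with 0 over the list alone (median 0.09, adjusted p = 0.656). KDR and ESAM no longer passed with total-count scaling (adjusted p = 0.174 and 0.151), nor EGFL7 with DESeq2 (0.0516). Stellate cell and fibroblast markers had 1 of 13 lower, LRAT (-0.56 ± 0.21, adjusted p = 0.0308, 0.0883 with voom), and 0 over the list alone (median -0.10, adjusted p = 0.48). Of 13 mitochondrially encoded genes, 4 rose, also over the list alone (median 0.25, adjusted p = 0.147). They were MT-ND6 (0.47 ± 0.18), MT-ND4L (0.32 ± 0.10), MT-ND4 (0.30 ± 0.10) and MT-ND5 (0.28 ± 0.11), of which MT-ND5 did not pass with total-count scaling (adjusted p = 0.19) and MT-ND6 not with the pairs as a block (0.18, adjusted p = 0.222). Without IRI- pre-transplant library 15 that list passed (median 0.32, adjusted p = 0.0411). Cytoplasmic ribosomal proteins did not pass (0 of 19, also over the list alone, median -0.10, adjusted p = 0.85), with RPLP0 at -0.24 ± 0.17.

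**Figure D2:**
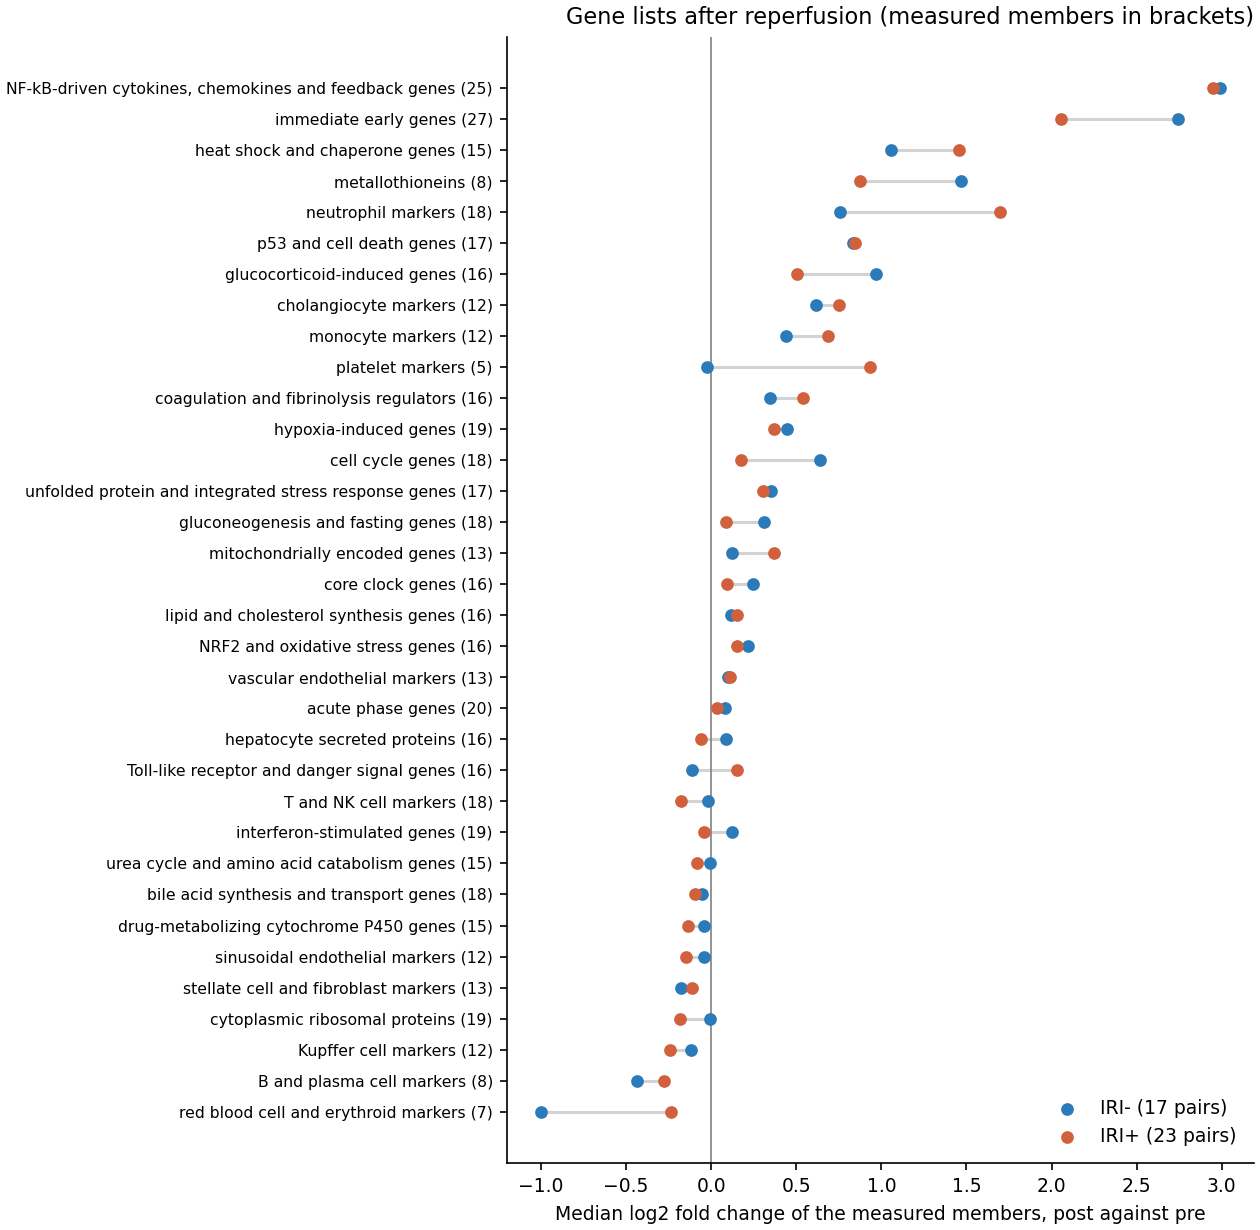
Median log2 fold change of the measured members of each gene list (horizontal axis) for post against pre, in IRI- (17 pairs) and IRI+ (23 pairs), with the lists on the vertical axis and the number of measured members in brackets. Immediate early genes (2.74 in IRI- and 2.05 in IRI+) and NF-kB-driven genes (2.99 and 2.95) lie furthest to the right.

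Over the genes called post against pre, the change ran with the mean change of the others in 39 of 40 pairs. The correlation across these genes was at least 0.196, the value of IRI- pair 1. The genes were called from all pairs together, so some agreement follows from their choice. IRI+ pair 23 ran the other way: its correlation was -0.734, and 20.8% of the called genes moved in the common direction. Along the mean change of the other 39 pairs, scaled so that their median pre-transplant library is at 0 and their median post-transplant library at 1, its pre-transplant library scored 0.60 and its post-transplant library -0.18. Without this pair 5859 genes were called.

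**Figure D3:**
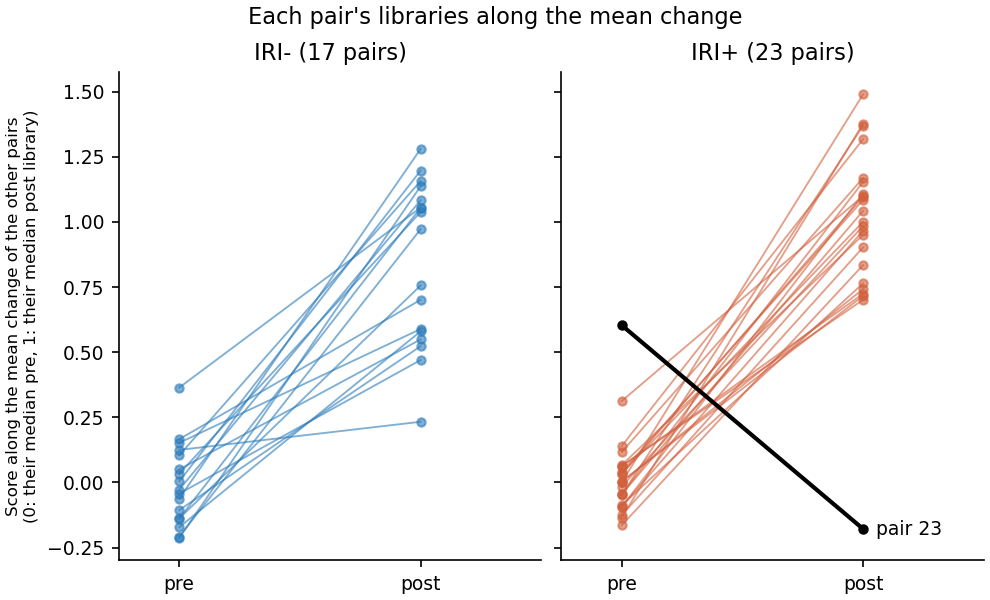
Score of each library along the mean change of the 39 pairs other than IRI+ pair 23 (vertical axis, no unit), with the libraries of a pair joined by a line, for IRI- and IRI+. The score is 0 for the median pre-transplant and 1 for the median post-transplant library of those 39 pairs, which set the axis themselves. The pre-transplant libraries of the other pairs lie between -0.21 and 0.36 and their post-transplant libraries between 0.23 and 1.49, while IRI+ pair 23, in black, goes from 0.60 to -0.18.

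Within the groups, heat shock genes, metallothioneins, neutrophil markers and glucocorticoid-induced genes had unequal medians. Heat shock genes rose in 12 of 15 cases in IRI- (median 1.06, adjusted p = 3.06e-16, 0.0208 with an estimated correlation) and in 15 of 15 in IRI+ (median 1.45, adjusted p = 7.33e-21, 0.00918 with an estimated correlation). Metallothioneins rose in 7 of 8 cases in IRI- (median 1.47) and in 6 of 8 in IRI+ (median 0.87), and glucocorticoid-induced genes in 10 of 16 (median 0.97) and 7 of 16 (median 0.50). Neutrophil markers rose in 3 of 18 cases in IRI- (median 0.76) and 15 of 18 in IRI+ (median 1.70), a contrast carried by IRI+ post-transplant library 15: without it the difference of the changes was -0.15 (adjusted p = 0.695). The test of the difference called none of these genes singly, and its results for the lists are given with the last comparison. Immediate early genes rose in 25 and 26 of 27 cases.

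In IRI- 2167 genes were called (1434 higher, 733 lower) and in IRI+ 4596 (2806 higher, 1790 lower). With the pairs as a replicate block the counts were 4154 (50.3% higher) and 7188 (47.6% higher). Under total-count scaling the higher genes made up 47% in place of 66.2% of the calls in IRI- and 41.6% in place of 61.1% in IRI+. The groups differ in size, and 50 random draws of 17 IRI+ pairs gave between 2277 and 4774 genes (median 3144), against 1895 in IRI- in the same kind of fit. Of the genes called higher in IRI-, 1379 were also called higher in IRI+, where independent lists would share 242.3, and of those called lower 599 were shared, where independent lists would share 79.01. No gene was called in opposite directions. Log2 fold changes of the groups correlated across genes with r = 0.888 (genes are not independent replicates).

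**Figure D4:**
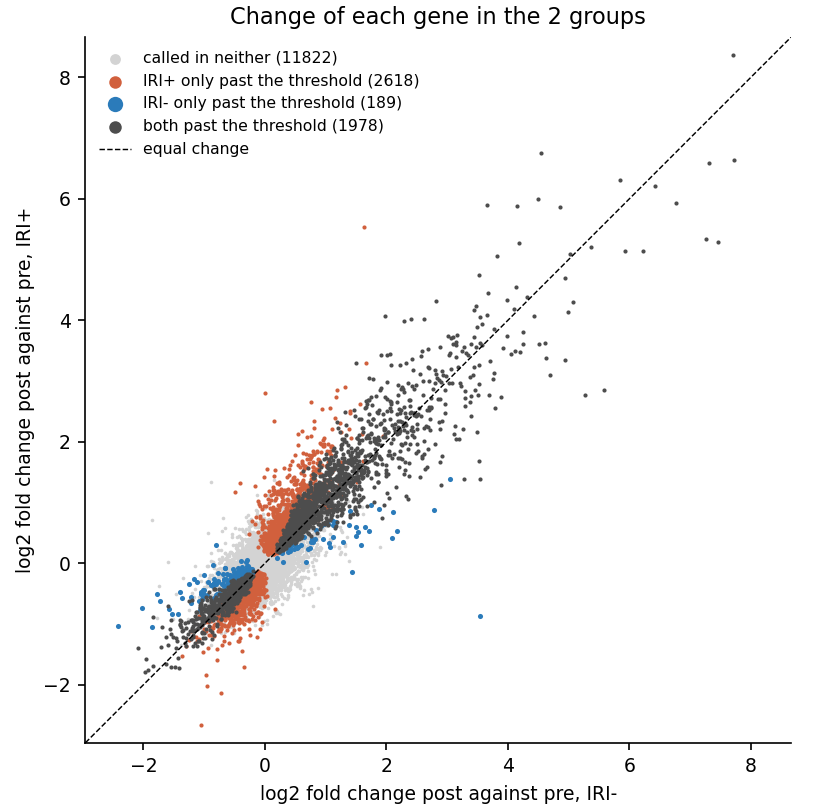
Log2 fold change post against pre of each of the 16607 genes in IRI- (horizontal axis, 17 pairs) and IRI+ (vertical axis, 23 pairs), coloured by the group in which the gene was called, with a dashed line of equal change. Of the 4785 genes called in either group, 98.9% changed in the same direction in both.

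The next comparison asked whether the grafts of the groups differed before transplantation. No gene passed edgeR's test (449 had an unadjusted p under 0.05, and the smallest adjusted p was 0.0592). DESeq2 called 2 genes (852 unadjusted) and voom 0 (400 unadjusted). Among the smallest p values were those of TFRC, the transferrin receptor (ENSG00000072274, chromosome 3, 196027183 to 196082189), at 50.6 ± 25.4 CPM in IRI- and 30.1 ± 12.5 in IRI+ (log2 fold change -0.75 ± 0.19, p = 0.000136, adjusted p = 0.529), and of CD69, an early activation marker of lymphocytes, at 0.354 ± 0.198 and 0.907 ± 0.715 CPM (1.33 ± 0.33, adjusted p = 0.529). The nuclear receptor NR4A2 was at 4.67 ± 3.59 and 18.3 ± 29.9 CPM (1.97 ± 0.53, adjusted p = 0.53) and the thyroid hormone deiodinase DIO2 at 0.0595 and 0.391 CPM. MMP3, a matrix protease, was at 0 in every IRI- library and at 0.294 CPM in IRI+, where 1 of 23 libraries held all of its reads.

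As groups, 21 of 34 lists passed camera's test with the preset correlation, but none did with an estimated correlation, where the smallest adjusted p was 0.214, and none with fry. The calls of 8 lists held whichever single library was left out, all of them higher in IRI+. These were interferon-stimulated genes (median 0.48, adjusted p = 5.83e-06, 0.352 with an estimated correlation, RSAD2 and IFI27 passing over the list alone), sinusoidal endothelial markers (0.28, 5.37e-06, 0.214 with an estimated correlation, FCN2 passing over the list alone), hypoxia-induced genes (0.23, 3.28e-05, 0.214 with an estimated correlation) and vascular endothelial markers (0.14, 4.13e-05, 0.214 with an estimated correlation). The others were metallothioneins (0.36, 7.01e-05, 0.352 with an estimated correlation, MT1M and MT1A passing over the list alone), glucocorticoid-induced genes (0.31, 7.01e-05, 0.352), lipid and cholesterol synthesis genes (0.24, 6.69e-05, 0.352) and monocyte markers (0.21, 0.00282, 0.367). MT1M was at 22.2 ± 14.1 CPM in IRI- and 62.1 ± 80.2 in IRI+ (1.48 ± 0.41, adjusted p = 0.638 over all genes), and FCN2, a lectin of sinusoidal cells, at 76.9 ± 21.6 and 103 ± 16.3 CPM (0.42 ± 0.13, adjusted p = 0.999).

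The other 13 calls ended without 1 or more single libraries. Cytoplasmic ribosomal proteins (median -0.33, adjusted p = 3.28e-05) went to 0.13 and 0.877 without IRI- pre-transplant library 15, and NF-kB-driven genes (0.44, 0.0013) to -0.01 and 0.404 without IRI+ pre-transplant library 23. Ribosomal proteins kept their call, at a smaller median, without all 5 libraries that stood apart (-0.116, adjusted p = 7.46e-07). B and plasma cell markers (-0.40, 0.00789) had an adjusted p of 0.056 without IRI- pre-transplant library 3, and NRF2 genes (-0.20, 0.00365) and T and NK cell markers (0.10, 0.00453) had 0.105 and 0.0633 without IRI- pre-transplant library 10, with medians of -0.10 and 0.05. Mitochondrially encoded genes were at 0.188 (adjusted p = 5.47e-09) without the 5 libraries that stood apart. In the main fit (0.07, 0.00789) they lost their call without IRI- pre-transplant library 14 (0.03, 0.092) or IRI+ pre-transplant library 22 (0.04, 0.054), and Toll-like receptor genes (0.15, 0.0126) without IRI- pre-transplant library 2 (0.0603) or that same IRI+ library (0.054). Kupffer cell markers (0.10, 0.0127) lost it without any of 6 single libraries, immediate early genes (0.44, 0.0248, NR4A2 passing over the list alone) without any of 15, acute phase genes (0.15, 0.0388) without any of 17 and gluconeogenesis genes (0.08, 0.0388) without any of 16. Hepatocyte secreted proteins (-0.08, 0.0484) lost it without any of 24 and cell cycle genes (-0.40, 0.0484) without any of 25. Several of these medians moved by over 1.5 times. Cell cycle genes went to 0.02 without IRI- pre-transplant library 3 and -0.24 without 9, immediate early genes to -0.04 without IRI+ pre-transplant library 23, and acute phase genes to 0.10 without IRI+ pre-transplant library 2 or 11. Hepatocyte secreted proteins went to -0.05 without IRI+ pre-transplant library 2 and -0.03 without IRI- pre-transplant library 15. Kupffer cell markers went to 0.06 without IRI- pre-transplant library 2 or 5 or IRI+ pre-transplant library 11, and to 0.05 without IRI- pre-transplant library 10 or IRI+ pre-transplant library 22. Gluconeogenesis genes went to between 0.03 and 0.04 without IRI- pre-transplant library 2, 7, 9, 10, 13, 14 or 15 or IRI+ pre-transplant library 14, and to 0.01 without IRI+ pre-transplant library 17. Without the 5 libraries that stood apart, B and plasma cell (adjusted p = 0.0627), immediate early (0.0908), acute phase (0.127) and hepatocyte secreted genes (0.233) were not called. The rest of these 13 lists were called. With an estimated correlation the adjusted p of the 13 lists lay at 0.352 or above. Of the lists not called, cytochrome P450 genes (-0.06, adjusted p = 0.108) held CYP3A7, a fetal form, which passed over the list alone (-1.64 ± 0.47). Heat shock genes (median 0.05), coagulation regulators (-0.002) and platelet markers (0.02) had a median and a test of opposite sign.

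After transplantation the 2 groups again differed little gene by gene. 2 genes passed, HSPA7 and MTCYBP18, and neither is covered by the rule for named genes, so both were chosen after their values were seen. HSPA7, an unprocessed pseudogene of the HSP70 family close in sequence to HSPA6 (ENSG00000225217, chromosome 1, 161606291 to 161608217), had a log2 fold change of 4.24 ± 0.76 (adjusted p = 0.00515), and without IRI+ post-transplant library 3 it was 0.72 ± 0.41 (adjusted p = 0.44). MTCYBP18, a processed pseudogene of the mitochondrial MT-CYB (ENSG00000244921, chromosome 5, 134923303 to 134924049), was at -4.04 ± 0.76 (adjusted p = 0.00783), and without IRI- post-transplant library 12 at -2.29 ± 0.68 (adjusted p = 0.148). An unadjusted p under 0.05 was reached by 2087 genes. DESeq2 called 23 genes (2611 unadjusted), voom 0 (1429 unadjusted) and a fit of these groups alone 0. The count ranged from 1 to 12 when single libraries were left out, and was 12 without IRI+ post-transplant library 12.

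The 5 genes with the smallest p under the rule did not pass. HIVEP3, a transcription factor (ENSG00000127124, chromosome 1, 41506365 to 42035925), was at 6.17 ± 2.26 CPM in IRI- and 12.1 ± 9.27 in IRI+ (0.96 ± 0.21, adjusted p = 0.0803, and 0.0142 with DESeq2). UBASH3B, a phosphatase, was at 3.84 ± 1.4 and 7.41 ± 5.69 CPM (0.94 ± 0.21), the protease gene ADAMTS9 at 13.9 ± 8.13 and 31.9 ± 27.2 CPM (1.19 ± 0.27), CYP1B1 at 0.76 ± 0.17 and ETV6 at 0.55 ± 0.13, each with an adjusted p of 0.0811.

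**Figure D5:**
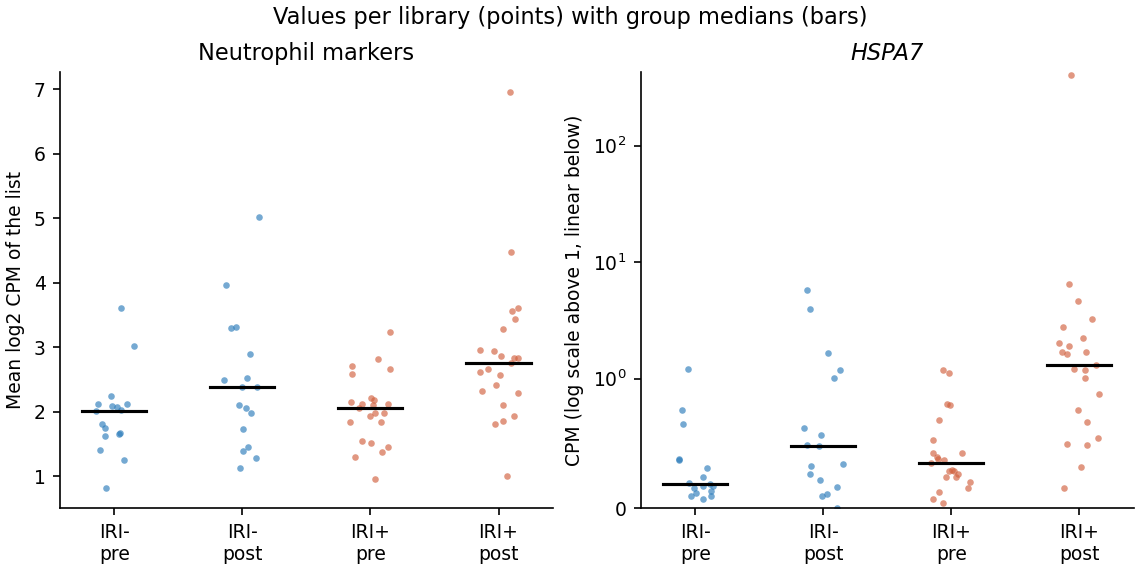
Mean log2 CPM of the neutrophil markers (left, vertical axis) and CPM of HSPA7 (right, log scale above 1 and linear below) in each library (points) of the 4 groups, with group medians as bars. 1 IRI+ post-transplant library reaches 6.96 for the neutrophil markers, against 4.48 for the next highest of its group and 5.02 for the highest IRI- post-transplant library, and another reaches 405 CPM of HSPA7, against 6.46.

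Of the 34 lists, 15 passed between the groups after transplantation, each with an adjusted p of 0.544 with an estimated correlation, and none passed with fry. Higher in IRI+ were heat shock genes (median 0.37, adjusted p = 3.83e-05, 0.24 without IRI+ post-transplant library 3 and 0.66 without IRI- post-transplant library 16), mitochondrially encoded genes (0.32, 3.83e-05, MT-ND4L and MT-ND6 passing over the list alone), lipid and cholesterol synthesis genes (0.34, 0.000294, LPIN1 over the list alone) and monocyte markers (0.45, 0.00272). Lower were ribosomal proteins (-0.45, 1.49e-05), hepatocyte secreted proteins (-0.19, 0.000294, APOA2 and AHSG over the list alone) and unfolded protein response genes (-0.25, 0.00272). These 7 calls held whichever single library was left out. Without the 5 libraries that stood apart, monocyte markers lost their call (median 0.19, adjusted p = 0.058) and the other calls held. Ribosomal proteins then had a far smaller median of -0.115 (adjusted p = 0.000204). IRI+ post-transplant libraries 4 and 15 held far larger mitochondrial shares (27.8% and 38.6%) than any IRI- post-transplant library (at most 18.9%), and without the 5 libraries that stood apart the median of mitochondrially encoded genes was 0.14 (adjusted p = 0.000204). HSPA6 had a log2 fold change of 1.51 ± 0.52 (adjusted p = 0.253 over all genes), the apolipoprotein gene APOA2 -0.82 ± 0.24 (0.216) and AHSG, a plasma carrier protein, -0.78 ± 0.23 (0.223).

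Neutrophil markers were higher in IRI+ (0.83, adjusted p = 0.00272), with 7 of 18 members passing over the list alone, among them FPR2 (1.29 ± 0.38) and CXCR2 (1.39 ± 0.44). Without IRI+ post-transplant library 15 the median was -0.03 (adjusted p = 0.217), and without IRI- post-transplant library 7 it was 1.25 (adjusted p = 3.72e-06). Interferon-stimulated genes (0.38, 0.00762, with MX1, MX2, IFI27 and RSAD2 passing over the list alone) went to 0.14 and 0.126 without IRI+ post-transplant library 17. Cell cycle genes (-0.94, 0.00593) lost their call without IRI- post-transplant library 3 (-0.40, 0.244) or 9 (-0.60, 0.202), and cytochrome P450 genes (-0.16, 0.0175, CYP3A7 passing over the list alone) without IRI+ post-transplant library 2 (-0.10, 0.12) or 11 (0.0637) or IRI- post-transplant library 12 (0.0733). Gluconeogenesis genes (-0.16, 0.0334) lost it without any of 13 single libraries (-0.10 without IRI- post-transplant library 6), glucocorticoid-induced genes (-0.15, 0.0424) without any of 17 (-0.09 without that library and -0.07 without IRI- post-transplant library 11), Toll-like receptor genes (0.25, 0.0481, TREM1 and TLR4 passing over the list alone) without any of 20 and vascular endothelial markers (0.18, 0.0481) without any of 21. Without IRI+ post-transplant library 15 the medians of these last lists were 0.05 and 0.08. In lists that were not called, single members passed over the list alone: AKR1B10 (-2.65 ± 0.73), HK2 (0.89 ± 0.27), MLKL (0.57 ± 0.18), BMAL1 (-0.46 ± 0.13), PLAU (1.11 ± 0.35), ITGB3 (1.07 ± 0.34) and TUBB1 (1.38 ± 0.47). Median and test differed in sign for red blood cell markers (median 0.54), clock genes (0.02), metallothioneins (-0.11), Kupffer cell markers (-0.05) and T and NK cell markers (-0.09).

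The last comparison asked whether the change from pre to post differed between IRI+ and IRI-. No gene passed edgeR's test (261 had an unadjusted p under 0.05, and the smallest adjusted p was 1), nor with the pairs as a replicate block (630 unadjusted), DESeq2 (637) or voom (167). The smallest p belonged to MAT2A, which makes S-adenosylmethionine (ENSG00000168906, chromosome 2, 85539165 to 85545280). It went from 68.4 ± 24.8 to 84.5 ± 30.1 CPM in IRI- and from 53.2 ± 14.9 to 118 ± 39.7 CPM in IRI+, a difference of log2 fold changes of 0.84 ± 0.21 (p = 0.000192, adjusted p = 1). MUC5B (-4.40 ± 1.15), STRIP2 (1.44 ± 0.44), GPR85 (1.44 ± 0.46) and SETD6 (0.35 ± 0.11) followed, each with an adjusted p of 1.

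Among the lists, heat shock genes rose more in IRI+ (median difference 0.47, adjusted p = 8.28e-07), and glucocorticoid-induced genes (-0.40, 4.32e-08) and gluconeogenesis genes (-0.15, 5.89e-05) rose less. These 3 calls held whichever single library was left out, and their adjusted p with an estimated correlation was 0.552, 0.302 and 0.522. They also held without the 5 libraries that stood apart, with medians of 0.44, -0.376 and, for gluconeogenesis genes, a smaller -0.088. HSPA8, the constitutive HSP70 chaperone, had a difference of 0.48 ± 0.25, IGFBP1 -1.06 ± 0.63, SLC25A25 -1.04 ± 0.45 and PCK1, the rate-limiting enzyme of gluconeogenesis, -0.80 ± 0.40, each with an adjusted p of 1. 8 further lists passed with the preset correlation and not with an estimated one (0.748 each), and each lost its call without single libraries, neutrophil markers (0.84, adjusted p = 0.00371) going to -0.15 and 0.695 without IRI+ post-transplant library 15. With the pairs as a replicate block the call of immediate early genes was lost (adjusted p = 0.146), as was that of T and NK cell markers (0.0507), whereas bile acid (0.0141), cytochrome P450 (0.000531), urea cycle (0.00996) and cell cycle genes (0.00684) gained one. These list tests also differed from the main ones in using voom values, so the changed calls cannot be put down to the block alone. Of the 23 lists not called, NF-kB-driven genes had a median difference of -0.39 (adjusted p = 0.299), hypoxia-induced genes -0.09 (0.156) and platelet markers 0.73 (0.133), the last with ITGB3 and TUBB1 passing over the list alone.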

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

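The splits of the samples were chosen before their results were seen, and of the tests of the 3 patterns weighed here only that of another recipient's library in IRI+ pair 23 was chosen before its result was seen. All other tests of those patterns, and the leaving out of single libraries, were chosen only after the result was seen.

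11 gene lists had a post against pre change that differed between IRI+ and IRI- by camera with the preset correlation, and none of them did with an estimated correlation. The median differences were 0.466 for heat shock genes (adjusted p = 8.28e-07, 0.552 with an estimated correlation), -0.395 for glucocorticoid-induced genes (4.32e-08, 0.302) and -0.153 for gluconeogenesis genes (5.89e-05, 0.522), and no single library ended these 3 calls. For gluconeogenesis genes the median was -0.088 (5.62e-05) without the 5 libraries that stood apart. For the other 8 lists the adjusted p with an estimated correlation was 0.748. Neutrophil markers differed by 0.842 (adjusted p = 0.00371), by -0.15 (0.695) without IRI+ post-transplant library 15, and by 1.18 (4.54e-07) without IRI- post-transplant library 7. Immediate early genes differed by -0.434 (0.00371), with a median of 0.09 and an adjusted p of 0.363 without IRI+ pre-transplant library 23, where the direction turned, and an adjusted p of 0.123 without its post-transplant partner and 0.128 without IRI- pre-transplant library 15. Metallothioneins differed by -0.594 (0.00371), with an adjusted p of 0.0575 without IRI+ post-transplant library 23, and a median of -0.28 (0.0801) without IRI- post-transplant library 17. Without the 5 libraries that stood apart their median was -0.129 (0.285). Mitochondrially encoded genes differed by 0.242 (0.0168). Without IRI- pre-transplant library 15 the median was 0.10 and the adjusted p 0.479, without IRI- post-transplant libraries 9, 13, 14 and 16 in turn 0.122, 0.0711, 0.0816 and 0.0794, and without IRI+ post-transplant libraries 4 and 15 in turn 0.124 and 0.256, the last with a median of 0.09. Hepatocyte secreted proteins differed by -0.111 (0.0207). Without IRI- post-transplant library 17 the median was -0.04 and the adjusted p 0.168, without IRI- pre-transplant libraries 3, 9 and 10 in turn 0.0656, 0.051 and 0.0708, and without IRI+ post-transplant libraries 2 and 15 in turn 0.0823 and 0.0761. Sinusoidal endothelial markers (-0.13, 0.0332), core clock genes (-0.139, 0.0482) and T and NK cell markers (-0.113, 0.0482) lost their calls without any of 19, 39 and 41 single libraries. Without the 5 libraries that stood apart, sinusoidal (-0.148, 0.00271) and T and NK cell markers (-0.188, 0.00271) were called, and clock genes (-0.124, 0.085) were not. The sinusoidal median was -0.07 without IRI- post-transplant library 4 or 17 or IRI+ pre-transplant library 10. That of the clock genes was -0.08 without IRI+ post-transplant library 2, -0.07 without IRI+ pre-transplant library 10 or 23 or IRI- post-transplant library 11, and -0.05 without IRI+ pre-transplant library 21. That of the T and NK cell markers was -0.07 without IRI+ post-transplant library 4, IRI+ pre-transplant library 17 or IRI- post-transplant library 11, -0.05 without pre-transplant library 10 of either group, -0.06 without IRI- post-transplant library 14 and -0.04 without 12.

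Other splits were drawn 100 times for each result, the real one included. Exchanging pre and post within drawn pairs gave at most 1179 genes over both groups, against the real 5752, at most 1 in IRI- against 2167 and at most 713 in IRI+ against 4596, so for these 3 counts chance can be excluded (1 of 100 splits, the real one). The 13 lists called post against pre are within what such splits give with the preset correlation (35 of 100 splits, highest other 17), and the 5 lists called with an estimated correlation are not (1 of 100, highest other 1). The groups were also redrawn as 17 and 23 of the 40 pairs. After transplantation 87 of 100 splits gave as many genes (real 2, highest other 518), so chance cannot be excluded. Before transplantation (real 0, highest other 352) and for the difference of the changes (real 0, highest other 2) any split reaches a count of 0 (100 of 100), so these splits test nothing. Most of these splits called few genes (medians 1, 5 and 0), but single splits that call 352 and 518 point to a structure of the samples, which was not tested further. Nor can chance be excluded for the genes with an unadjusted p under 0.05 after (real 2087, highest other 3685, 14 of 100 splits) and before transplantation (real 449, highest other 3139, 78 of 100). The same holds for the lists called after transplantation (real 15, highest other 23, 26 of 100), those of the difference (real 11, highest other 18, 42 of 100) and the excess of 2429 genes called in IRI+ over IRI- (highest other 4099, 15 of 100). The 21 lists called before transplantation were more than any other split gave (1 of 100 splits, highest other 18). That result is 1 of the several split tests given here, without adjustment for their number. The count also depends on single libraries and was 15 without IRI+ pre-transplant library 22, inside the range of the other splits. Chance is therefore not excluded for it. 13 of the 21 calls ended when 1 library was left out, and 0 lists passed with an estimated correlation or fry.

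IRI+ pair 23 changed opposite to the other pairs. On the scale of the other 39 pairs its pre-transplant library scored 0.60 and its post-transplant library -0.18. Of those other pairs, which set the scale themselves, 0 of 39 pre-transplant libraries scored over 0.5 and 2 post-transplant libraries under 0.5. Exchanged pre and post labels are thus a candidate explanation. Low depth is argued against, because the totals of its libraries, 22069482 and 25300354 counts, lay above the lowest of the 73 other libraries that did not stand apart (11361868). Degraded RNA cannot be decided, because no measure of RNA integrity was used. The higher mitochondrial share of its libraries was 13.8%, inside the range of those 73 (up to 18.9%). IRI+ pre-transplant library 22 (18.5%) and IRI- post-transplant library 17 (18.2%) also lay inside that range, yet stood apart on the second component. A library of another recipient in IRI+ pair 23 is argued against, because with the labels exchanged back the deviations of the pair's libraries correlated at 0.521, the highest for that library among all candidate partners, against -0.0731 as labelled. No biological explanation was tested, and a recipient whose liver held the response before and not after transplantation stays open.

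HSPA7 and MTCYBP18 were the genes called between IRI+ and IRI- after transplantation. HSPA7 reached 405 CPM in IRI+ post-transplant library 3 and at most 6.46 CPM elsewhere, and without that library its adjusted p was 0.44. Reads shared between HSPA7 and HSPA6 in a fixed ratio are argued against, since the ratio of HSPA7 to HSPA6 was 0.709 in that library and between 0.0236 and 0.167 in the 24 other post-transplant libraries with at least 10 CPM of HSPA6, and what else may set that library apart was not tested. MTCYBP18 was at 39.1 CPM or more in both libraries of 2 IRI- pairs and at 8.24 CPM or less in all others, and without those pairs its log2 fold change was -0.26 ± 0.41 (adjusted p = 0.903), which is consistent with a level that belongs to those grafts at both times. No biological explanation was tested for either gene.

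Neutrophil markers rose after transplantation (adjusted p = 0.00433, 0.784 with an estimated correlation) and were higher in IRI+ after it (0.00272, 0.544 with an estimated correlation). For the difference between the groups 1 library may decide: without IRI+ post-transplant library 15, whose mean level of these markers was 6.96 log2 CPM and whose mitochondrial share was 38.6%, the adjusted p was 0.217 and the median -0.03, while without IRI- post-transplant library 7 the median was 1.25 (3.72e-06). For the rise after transplantation that library is not the whole cause, as the list kept a median of 0.66 (adjusted p = 0.00203) without it, with the preset correlation. A lower share of hepatocyte RNA alone is argued against for the rise, because it would raise markers of all other cell types alike. The per-pair change of neutrophil markers exceeded that of T and NK cell markers by 0.71 ± 0.188 (SE, n = 40). It exceeded that of red blood cell markers (mean -0.40, SE 0.214) by 1.09 ± 0.261, which argues against more blood of an unchanged make-up in the biopsy. Blood with more neutrophil RNA for its red blood cell RNA after transplantation is not decided by these values. An influx of neutrophils and a change of expression in resident cells stay open and were not tested.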

How the results depend on the processing

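The alternatives that leave out the 5 libraries that stood apart, IRI+ pair 23, the 2 IRI- pairs highest in MTCYBP18 or single libraries, and the draws of 17 IRI+ pairs, were chosen only after the result was seen; the others were planned. No named gene or list was called in the opposite direction under the alternatives for which directions were kept. In the fits without single libraries, only fold changes of HSPA7 and MTCYBP18 and list medians with their adjusted p were kept. The draws of 17 IRI+ pairs kept only counts of genes. Medians of lists changed sign as their calls were lost. Without IRI+ pre-transplant library 23, immediate early genes went to -0.04 before transplantation and to 0.09 for the difference of the changes, and NF-kB-driven genes to -0.01 before transplantation. Neutrophil markers went to -0.03 after transplantation and to -0.15 for the difference without IRI+ post-transplant library 15, and before transplantation ribosomal proteins went to 0.13 without IRI- pre-transplant library 15 and cell cycle genes to 0.02 without 3. Without all 5 libraries that stood apart, ribosomal proteins before transplantation were at -0.116 and stayed called (camera adjusted p = 7.46e-07). The fixed replicate block put the difference of immediate early genes at 0.05, and leaving out the 5 libraries put that of mitochondrially encoded genes at -0.05. Over the alternatives apart from single libraries and the draws of 17 IRI+ pairs, 1743 values of named genes post against pre kept their side of the threshold. Of the rest, 32 lost and 17 gained a call, and the numbers were 452, 11 and 13 for lists. Between the groups lists were less stable: before transplantation 332 values kept their side, 70 lost and 6 gained a call, after it 340, 59 and 9, and for the difference of the changes 403, 55 and 18, while of the named genes 0, 11 and 0 gained one in turn. The cause was not tested except where the alternative uses fewer samples or a stricter threshold.

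Requiring also a 2-fold change left 1010 of 5752 genes post against pre, 836 of 2167 in IRI- and 1152 of 4596 in IRI+. With the pairs as a fixed replicate block the counts were 8176, 4154 and 7188, with the pair as a random block in voom 8057, 4369 and 7072, and with the fixed block and without IRI+ pair 23 they were 8300, 4177 and 7472. Of the 5752 genes, 5650 were also called with the fixed block. Among the named genes and lists the block over all pairs changed no call other than those given beside the results. With the block, on voom values, and without IRI+ pair 23 the difference also passed for NF-kB-driven genes (adjusted p = 0.0183), p53 genes (0.00544) and platelet markers (0.0469), and did not for clock genes (0.147). Other settings gave between 4917 and 6848 genes for both groups together.

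Between the groups before transplantation, where 0 genes were called, DESeq2 called 2, no filter on low counts 21 and a mean CPM of at least 1 called 2. After transplantation, where 2 were called, DESeq2 called 23, no filter 65, voom 0, voom with the random replicate block 0 and a fit of only these groups 0, and 1 was called with 2 surrogate variables, without the 5 libraries, without these and IRI+ pair 23, and without the 2 pairs highest in MTCYBP18. For the difference of the changes, where 0 were called, no filter gave 3.

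Of the lists, 13 post against pre became 5 with an estimated correlation. Between the groups an estimated correlation and fry each left 0 before transplantation, 0 after it and 0 for the difference of the changes, and without the 5 libraries and IRI+ pair 23 the difference kept 5 of 11. The clock list also lost its call with a mean CPM of at least 1 (adjusted p = 0.121), and gluconeogenesis genes gained one with no filter (0.0147) or surrogate variables (0.0268).

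Leaving out each of the 80 libraries in turn gave 5491 to 6307 genes post against pre, 1865 to 2365 in IRI-, 4154 to 4955 in IRI+ and 0 to 0 for the difference of the changes. Before transplantation it gave 0 to 1, with 1 gene without any of 17 libraries. After it the range was 1 to 12: 12 without IRI+ post-transplant library 12, 6 without 23, 5 without 7 or 10, 4 without 6 or 13, 1 without 3, 4 without IRI- post-transplant library 13 and 1 without 12. The lists called ranged from 13 to 14 post against pre, 15 to 23 before transplantation, 10 to 18 after it and 6 to 14 for the difference of the changes, the last with 7 without IRI+ post-transplant library 4 or 15 and 6 without 23.

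In the simulation, 41.8% of genes changed 1.5-fold were recovered between the groups before transplantation and 58.2% after it. The share was 22.4% for the difference of the changes, against 67.2% post against pre. The simulation gave a gene the same mean and spread in all groups and held no pair effects. Each of these shares rests on 67 changed genes in a single draw. The gap between before and after transplantation can therefore not be read as a difference in power. Depth was not varied in the simulation, so its own part in these limits was not tested. Fits of only the groups compared were not run for the mean over both groups and the difference, which need all 80 libraries.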

Other observations

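Every test in this part was chosen after the data had been seen. Genes were grouped by the letters their symbols share, which gave 254 families of at least 8 protein-coding members, and each was tested for an excess or a deficit of higher and of lower calls post against pre (508 Fisher's exact tests, two-sided, 13969 genes, Benjamini-Hochberg adjusted). An excess of lower calls was found in 3 families (adjusted p under 0.05), among them the zinc finger genes of the ZNF family. Of these ZNF genes, 159 of 443 fell (35.9%, against 15.2% of all genes, adjusted p = 3.15e-25) and 61 rose. The median log2 fold change of the ZNF genes was -0.155, and 0 of 10000 random lists matched on mean expression were as low (range -0.098 to 0.033). Fisher's test and these random lists treat genes as independent and their fold changes as fixed. Neither measures how the result varies over grafts, and pre and post were not exchanged within pairs for any family. Over 16 settings between 129 and 216 ZNF genes fell, with 202 under total-count scaling. Members of the tumor necrosis factor receptor family TNFRSF rose in 12 of 16 cases (median 0.92, adjusted p = 0.000803, 9 to 12 over the settings).

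12 more families had an excess of higher calls. Of the splicing factors named SRSF, 9 of 12 rose (median 0.20, adjusted p = 0.00716, 5 with total-count scaling), of the ribosomal RNA processing genes named RRP 7 of 8 (0.29, 0.00716, 3 with total-count scaling), of the UTP genes of the small subunit processome 8 of 11 (0.29, 0.013, 5 with total-count scaling) and of the DEAD-box helicases DDX 17 of 34 (0.21, 0.00716, 11 with total-count scaling). They do not stand for RNA processing as a whole, which was not tested: 0 of 10 EXOSC and 0 of 13 LSM genes rose, and of 16 INTS genes 2 rose and 4 fell. The DUSP phosphatases rose in 11 of 19 cases and fell in 3 (adjusted p = 0.0138), and the KLF transcription factors rose in 9 of 14 and fell in 4 (adjusted p = 0.0145). The others were genes whose symbols begin with IL (21 of 46 rose, adjusted p = 0.00771), HSPA (8 of 11, 0.013), S (11 of 19, 0.0138), MT (12 of 22, 0.0143), BCL (10 of 18, 0.025) and TNFAIP (6 of 8, 0.0307), of which S, MT and BCL each join genes that share letters and not descent. None of 49 mitochondrial ribosomal protein genes named MRPL rose (adjusted p = 0.00619), and 4 fell. Over the 16 settings between 0 and 4 of them rose and between 3 and 11 fell, with medians from -0.163 to 0.004.

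Pairs differed in the size of their change. IRI- pair 1 barely moved: over the called genes its change correlated at 0.196 with the mean change of the others. In that pair 55.8% of the called genes moved in the common direction, and the median change of the called higher genes was 0.02. In IRI- pair 12 the correlation was 0.897 and that median 0.98. Averaged over a list, sinusoidal endothelial markers were lower in most pairs by a small amount (mean change -0.14, SE 0.044, higher in 8 of 40 pairs), although no member passed the test without the block. The mean change was -0.24 (SE 0.107, higher in 12 pairs) for B and plasma cell, -0.40 (SE 0.214, 13 pairs) for red blood cell and -0.14 (SE 0.076, 18 pairs) for stellate cell markers, 0 (SE 0.047, 18 pairs) for Kupffer cell markers and 0.09 (SE 0.049, 23 pairs) for vascular endothelial markers.

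Some abundant liver and stress genes had few counts. Over all 80 libraries complement factor CFB held 15 reads in 12 libraries, against 22345 for its neighbour C2, CSNK2B held 0, and the globin genes HBA1 and HBA2 held 698 and 451, against 80297 for HBB. Of 198 protein-coding genes between 28 and 34 megabases of chromosome 6, 95 (48%) held fewer than 800 reads in total, against 34% of 836 genes on the rest of the chromosome and 31.1% of 18565 genes on the others. Low counts of these genes cannot be read as low expression, since the annotation and the counting of shared reads are not given in the sources used here.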
